A study of Drosophila melanogaster with 2 samples.

How the data were processed

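ChIP-seq of 2 biological replicates of the CG42726-eGFP line was used, with chromatin from whole embryos fragmented by sonication to a size range of 200 to 800, per the labels. The labels do not say more about separate collections than that the replicates are biological. The 8 peak lists are of 2 kinds. Each ranked list holds regions in order with their IDR values, and each thresholded list holds the regions that passed. There is a pair for each replicate and for the pooled reads, and a pair that compares the biological replicates (the main list). The build is dm6, per the labels. The aligner, the peak caller and their versions are not given in the sources used here. The deposited file records name a control among the parents of the lists, and it was not analysed here.

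The signal of each region is the authors' own value from the deposited lists, and is used only to describe and rank regions within a list. The −log10 of the global IDR is a deposited column of the ranked lists. The score in the columns of the deposited ranked lists that were made from pseudoreplicates (pooled or single reads split at random) was used for the benchmark correlation. The ranked list between biological replicates holds a signal column for each of the 2, but the file does not say which column is which replicate, so they entered only the correlation. Signals given for replicate 1 or 2 come from that replicate's own thresholded list. In each thresholded list the lowest −log10 IDR kept was just above 2, per the deposited ranked lists, which is an IDR of 0.01. Of the 2894 ranked regions of the main comparison at this limit, 142 are not in the thresholded list. The records name a further parent for the thresholded lists and do not say what it removed.

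The files hold no counts, so the depth and the precision it gives are unknown. Intervals are exact Clopper-Pearson 95% intervals over regions or genes and cover counting error only. Genes and starts were taken from the Ensembl annotation of the same assembly (release 115), without transposable elements, and sequence from the RefSeq assembly, whose chromosome lengths were checked against the annotation. Summits on unplaced sequences were left out of location, gene and sequence tests (5 in the main list).

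Each base belonged to the first fitting class among promoter (500 bp to either side of any start), 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. The non-coding exon class was added to the classes chosen at the start so that each base had one. Random positions were drawn 1000 times on the same chromosomes. Chromosome shares used exact binomial tests against sequence without N. A gene had a region when a summit lay within 1 kb of any of its starts. In the alternative by nearest start, each summit counted for the gene with the nearest start at any distance, without the 1 kb limit. Gene lists were matched by symbol, and 5 symbols were not found under the name used. Sequences were counted on either strand within 50 bp of the summit and in flanks of the same total length, and compared by exact McNemar tests. The reversed-sequence control was left out for GAGAGAG and runs of adenines, which equal their own reversal, and for CA repeats, whose reversal is the same repeat shifted by a base. For the tagged gene, a region counted when any of its bases lay in CG42726 or within 5 kb. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05.

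The tests, gene lists, sequences, main list and most alternatives were fixed before the data were examined. The genes named are those with starts nearest to the 15 regions of highest signal, up to 3 members of each gene list with a summit within 1 kb by signal, and CG42726 whatever its values. Both genes are named where starts tie. The remaining members of the insulator list, and the genes named in the closing section, were named after their values were seen. Alternatives were the pooled list, the regions with a signal above the median, each replicate's list alone, other windows, starts, backgrounds, flanks and sequence lengths. With 1 group there is no comparison between groups and no test of outlying samples.

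The functions were tested on simulated regions first. For the promoter share, random positions were called in 0 of 20 runs, and a planted excess of 25.9 percentage points came back as 25.9 (2747 regions). For the fixed sequences, 0 calls arose in 5 runs on random positions, and a DRE planted in 5% of regions came back as a difference of 4.95 points. For 8-mers the planted DRE came first and passed in 5 of 5 runs. For gene lists, 20 runs of random genes gave 2 list calls in all, and a list drawn 5 times as often was called in 20 of 20 runs (13968 genes). These genes were drawn independently with a summit at a start, and false calls were counted for protein-coding lists only. The sharing of regions by clustered genes was not simulated. For the replicate overlap, 50% shared regions came back as 50.5%. For the promoter signal, 1 of 10 runs without a difference was called and 10 of 10 with a ratio of 1.3. For the chromosome shares, 0 calls arose in 20 runs. Simulated regions lay on 2L, 2R, 3L, 3R and X only, so false calls on chromosomes 4 and Y were not tested.

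The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.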

Results

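Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos of 0 to 24 hours. The embryos came from a transgenic line that expresses the CG42726 protein fused to enhanced green fluorescent protein (eGFP), and the fusion protein was pulled down with an antibody against GFP. CG42726 is an annotated protein-coding gene with no name beyond its gene number. The series holds 1 group of 2 biological replicates, so no groups were compared, and the question the data address is where in the genome the tagged protein was found. The files list called regions with a signal value per region and give no read counts, so the depth of each replicate is unknown. Coordinates are on dm6.

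The main list held 2752 regions that passed the irreproducible discovery rate (IDR) limit between the biological replicates, 2747 of them on chromosomes 2L, 2R, 3L, 3R, 4 and X. The regions had a median width of 296 bp, covered 780 kb in all, and had a median signal of 102. The list made from pooled reads held 4044 regions. Replicate 1 alone gave 2803 regions and replicate 2 alone gave 1629.

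Regions at the tagged gene were called with signals below the median of the main list. CG42726 (FBgn0261679) lies on 3R from 15348048 to 15350391 on the plus strand. In the main list 3 regions touched the gene or the 5 kb to either side. The strongest, at 15342824 to 15343119, had a signal of 89.9 and lay at the promoter of Nagk, 138 bp from its start, and 60.3% of the list's regions had a higher signal. In the ranked list between the replicates, 1.31% of regions had a higher signal than it. A region at 15350205 to 15350500 (signal 67.1, rank 2449) had its summit within CG42726, where the annotation also places CG42727 and Trs33. The other region, at 15351460 to 15351755 (signal 64.3, rank 2540), lay at the promoter of Tmtc4. Replicate 1 alone had 3 regions within the same distance, and replicate 2 alone had 0.

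The regions with the highest signal lay at Kr-h1 on 2L, the gene of a zinc finger transcription factor that acts in the response to juvenile hormone. Its gene body spans 6082603 to 6096498. The strongest region of the list, at 6088282 to 6088734, had a signal of 13437.1 and lay in an intron of Kr-h1, 2904 bp from a start that Kr-h1 shares with CG45075. The next, at 6078862 to 6079296 with a signal of 5917, lay upstream of Kr-h1 in an exon of the non-coding RNA gene lncRNA:CR9162. The third, at 6081265 to 6081600 with a signal of 2843, was intergenic and lay 1163 bp from the nearest Kr-h1 start. The strongest of these was 131 times the median of the list and 9.42 times the fourth region, which lay 72 bp from the start of MESK2 (signal 1426). The same order held in each replicate, with signals of 7454, 3307 and 1582 in replicate 1 and 5996, 2601 and 1256 in replicate 2. The ratio of the first to the fourth region was 9.18 in replicate 1 and 9.16 in replicate 2. No control immunoprecipitation was analysed here, so the signal of these regions with an untagged line is unknown.

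**Figure D1:**
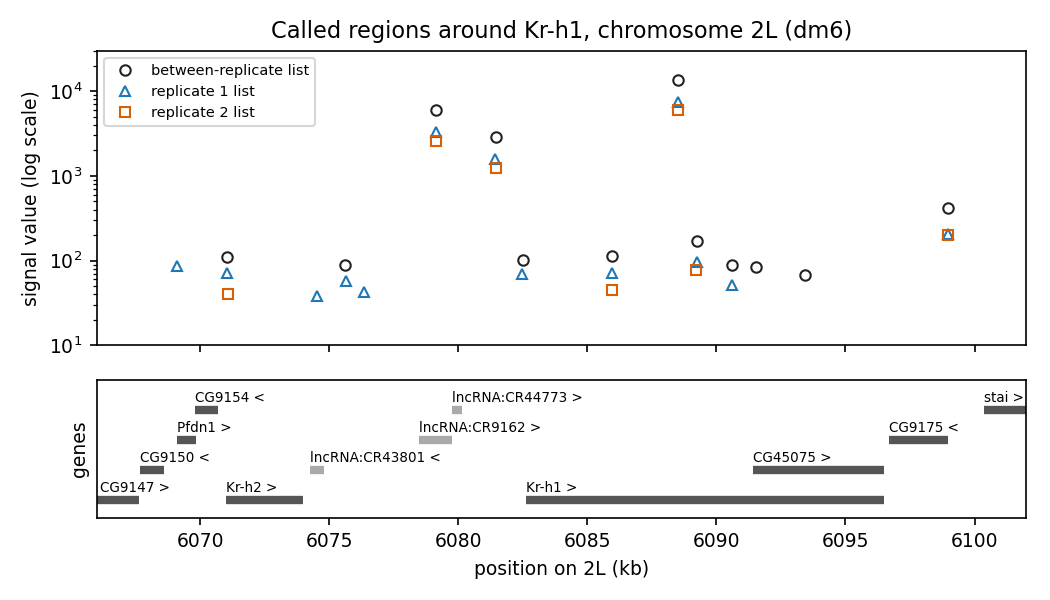
Signal value (log scale) of each called region in the main list and in each replicate's own list against its summit position on 2L in kb, with annotated genes below (dark bars protein-coding, pale bars non-coding, arrowheads the direction of transcription). The 3 regions at Kr-h1 stand at 13437.1, 5917 and 2843 in the main list, above the other regions of the locus.

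From the fourth region on, the 15 regions of highest signal all lay within 500 bp of an annotated start. After MESK2 came Rpn6, a subunit of the proteasome lid, with a signal of 901 at 90 bp from its start. Sumo, which encodes the small ubiquitin-like modifier, had a signal of 849.6 at 21 bp. The region at Daxx, the gene of a histone chaperone, had a signal of 771 at 57 bp. Pym had 736, jagn 692, CG2924 671 and Creld 656. Capr had 633, CG30015 630.3, CG11964 627 and bun 627. Of the whole list, 59 regions had a signal above 400 and up to 1000, and 4 were above 1000.

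The replicates shared most of the smaller list. Of the 1629 regions of replicate 2, 1245 (76.4%, exact binomial 95% interval 74.3 to 78.5) overlapped a region of replicate 1 by at least 1 bp, and 1255 of the 2803 regions of replicate 1 (44.8%) overlapped one of replicate 2. On the main chromosomes the share was 78.7%, against 1.10% for regions shuffled within their chromosomes (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give). Regions of replicate 2's own ranked list, drawn to match the share at promoters, overlapped replicate 1 in 9.29% of cases. This second expectation was chosen after seeing the data. The 1548 regions found only in replicate 1 had a median signal of 51.8, against 86.1 for those it shared. Of these 1548, 85.8% overlapped a region of replicate 2's ranked list. That list holds 128839 regions, and the share that would overlap without agreement was not computed. The ranked regions overlapped, taking the strongest for each, stood at a median signal percentile of 95.1 in that list.

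Across the 2752 regions of the main list, the signals of the 2 replicates had a Spearman rho of 0.571 and a Pearson r of 0.71 on the log10 scale. Without the 3 Kr-h1 regions the Spearman rho was 0.57 and the Pearson r 0.69. These are correlations across regions, which are not independent replicates, so no p is given. For the same list, reads pooled and split at random gave a rho of 0.723 over the 2748 regions with a match.

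Called regions lay mostly at promoters. Of 2747 summits, 2188 (79.7%, exact binomial 95% interval 78.1 to 81.1) fell within 500 bp of an annotated start, against 13.7% of random positions, a ratio of 5.82 (one-sided permutation p = 0.001, the smallest that 1000 sets can give; adjusted p = 0.001). Introns held 7.46% of summits against 39.2% of random positions, intergenic sequence 7.57% against 27.4%, and coding exons 3.49% against 13.7%. In 3' UTRs the share was 1.02% against 4.38% (each of these 4 classes with permutation p = 0.001 and adjusted p = 0.001). Summits were also fewer in 5' UTRs away from starts (0.437% against 0.773%, permutation adjusted p = 0.026) and in non-coding exons (0.364% against 0.807%, adjusted p = 0.005). Promoter summits lay a median of 42 bp from the nearest start, and 83.6% were within 100 bp. At 660 of the 2188 (30.2%), the starts of more than 1 protein-coding gene lay within 500 bp.

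**Figure D2:**
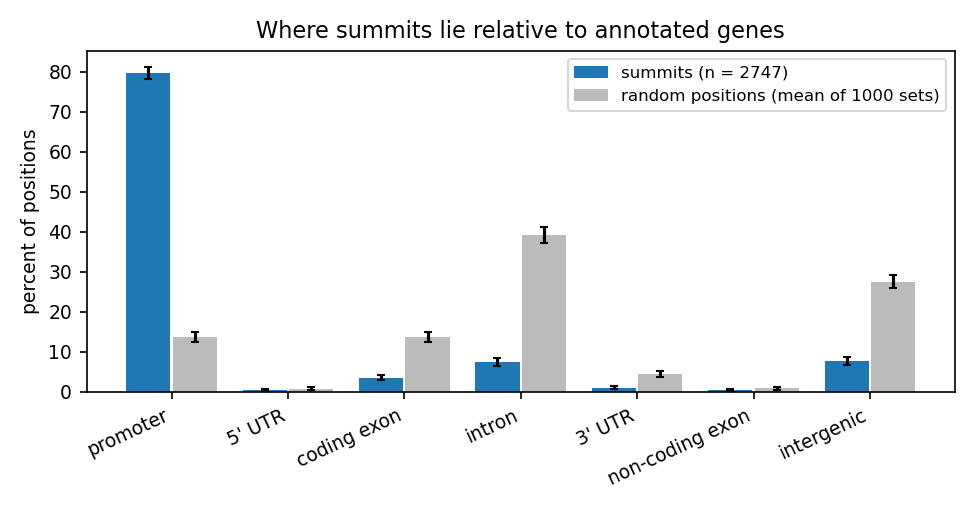
Percent of summits (blue, n = 2747, exact binomial 95% intervals) and of random positions on the same chromosomes (grey, mean of 1000 sets with the central 95% of sets) in each class of annotated sequence. Promoters, defined as 500 bp to either side of a start, hold 79.7% of summits and 13.7% of random positions.

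Promoter regions had a median signal of 109 (interquartile range 82.1 to 160.2, n = 2188) and the other 559 regions one of 81.6 (69.7 to 113). The difference of 27.1 gave p = 1e-05 in a two-sided permutation test with 100000 resamples, the smallest p it can give. In the list of replicate 2 alone the difference was 2.22 (permutation p = 0.264), and in that of replicate 1 alone it was 14.6.

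The density of summits differed between chromosomes. Chromosome 2R held 657 summits, 25.99 per Mb, which is 1.297 times its share of the sequence (two-sided exact binomial test, adjusted p = 3.06e-12). The 523 summits of 2L came to 1.11 times its share (exact adjusted p = 0.0172) and the 425 of X to 0.903 times (adjusted p = 0.0297). The small, largely heterochromatic chromosome 4 held 3 summits, 0.112 times its share (exact adjusted p = 3.59e-08), and Y held 0 (adjusted p = 1.32e-29). On 3L and 3R the ratios were 0.948 and 0.945 and did not pass (exact adjusted p = 0.177 and 0.134). Against the share of protein-coding starts, 2R stayed higher (ratio 1.17, exact adjusted p = 3.34e-05) and 4 lower (0.148, adjusted p = 3.34e-05), while 2L, X and Y no longer passed (adjusted p = 0.876, 0.0816 and 0.122). The 2L call was lost in replicate 1 alone (ratio 1.08, exact adjusted p = 0.0663) and the X call in replicate 2 alone (0.916, adjusted p = 0.155), while 3L passed as lower in replicate 2 alone (0.892, adjusted p = 0.0438). The ratio of chromosome 4 was 0.478 in replicate 1 alone and 0 in replicate 2 alone. Few candidates lay there, as the ranked list between the replicates held 117 regions on chromosome 4 of 140257 in all. The ranked lists of replicates 1 and 2 held 784 and 87. The low count on chromosome 4 in the main list was not separated from this shortage of candidates in replicate 2.

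Genes of cytosolic ribosomal proteins, insulator proteins and transfer RNAs had called regions more often than other genes in the main list and in every alternative tried. Of the 13945 protein-coding genes on chromosomes with summits, 2866 (20.6%) had a summit within 1 kb of a start. Of the 27 fixed lists, 5 had one more often than other genes, 5 less often, and 17 did not pass (two-sided Fisher's exact test, Benjamini-Hochberg over the 27 lists). Neighbouring genes share regions, so genes within a list are not independent.

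Among 85 cytosolic ribosomal protein genes, 44 had a summit within 1 kb (51.8%, odds ratio 4.20, exact adjusted p = 1.12e-09), led by RpL32 (signal 593), RpS2 (516) and RpL7 (401). Of 44 translation initiation factor genes, 17 had one (38.6%, odds ratio 2.44, exact adjusted p = 0.0202), led by eIF3f1 (469), eIF3a (374) and eIF2gamma (357). Of 73 mitochondrial ribosomal protein genes, 25 had one (34.2%, odds ratio 2.02, exact adjusted p = 0.0168), led by mRpL4 (486), mRpL17 (383) and mRpL33 (303). The summits assigned to mRpL17 and mRpL33 lay nearer to the starts of Tudor-SN and norpA. With each summit assigned to its nearest start alone, at any distance, the odds ratio was 0.786 for mitochondrial ribosomal proteins (exact adjusted p = 0.748) and 1.46 for initiation factors (adjusted p = 0.399). With genes that have a ranked region as the background, chosen after seeing the data, the mitochondrial list did not pass (odds ratio 1.84, exact adjusted p = 0.0668). Nor did it pass in replicate 1 alone, at 2 kb or among regions above the median signal (exact adjusted p = 0.123, 0.097 and 0.12). The initiation factor list did not pass at 2 kb or above the median signal (exact adjusted p = 0.056 and 0.111).

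Genes of insulator and promoter-binding proteins had the highest share in the main list, 12 of 17 (70.6%, odds ratio 9.31, exact adjusted p = 5.46e-05). In replicate 2 alone their odds ratio was 4.79, below that of transfer RNA genes (6.88). BEAF-32, which encodes a boundary element factor, had a summit 17 bp from a start with a signal of 314. Ibf1 and Ibf2, divergent genes of insulator binding factors, shared a region of signal 174. The other members with a summit were CTCF, Chro, Cp190, Trl, mod(mdg4), nej, pita, pzg and su(Hw).

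Genes of transfer RNAs, transcribed by RNA polymerase III, had a summit within 1 kb in 178 of 290 cases (61.4%, against 17.7% of all other annotated genes, odds ratio 7.37, exact adjusted p = 2.15e-58). The 178 genes were reached by 137 summits, since many lie in clusters. The strongest lay at a cluster on 2R with tRNA:Glu-CTC-1-1, tRNA:Glu-TTC-1-1 and tRNA:Glu-TTC-1-2 (signal 273), near the start of mrj. Of 32 small nuclear RNA genes 11 had a summit (34.4%, exact adjusted p = 0.0743), among them snRNA:7SKa (398) and the neighbours snRNA:U6:96Ab and snRNA:U6:96Ac (306). Small nucleolar RNA genes had one in 18.96% of 269 cases (odds ratio 1.04, exact adjusted p = 0.954), with the strongest at snoRNA:Psi18S-1275 (328), snoRNA:Psi28S-2648 (283) and snoRNA:Psi18S-920 (244), which lie by ribosomal protein genes. Their result turned on the window, with an odds ratio of 2.14 at 2 kb (Fisher's exact test, adjusted p = 3.78e-08), 0.427 at 500 bp (adjusted p = 0.000288) and 0.271 by nearest start (adjusted p = 1.82e-06).

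Chemoreceptor, cuticle protein, cytochrome P450, immune effector and histone genes had called regions less often. Summits lay within 1 kb of 5 of 179 chemoreceptor genes (2.79%, odds ratio 0.11, exact adjusted p = 5.59e-11), with Gr97a (99.8), Or71a (74.5) and Ir76a (73.6) the strongest. The summits of Gr97a and Or71a lay nearer to the starts of CG5521 and Plp. Of 114 cuticle protein genes 4 had one (3.51%, odds ratio 0.139, exact adjusted p = 1.41e-06), led by Cpr65Eb (72.0), Lcp9 (67.5) and Edg78E (65.2). The summit of Lcp9 lay nearer to egg. Of 85 genes with a cytochrome P450 symbol 5 had one (5.88%, odds ratio 0.24, exact adjusted p = 0.000909). The strongest of these, Cyp1 (197), is a cyclophilin that the symbol rule took in, followed by Cyp6a22 (81.0) and Cyp9f3 (79.3). With nearest starts alone the P450 odds ratio was 0.513 (exact adjusted p = 0.134). Of 45 immune effector genes 2 had one (4.44%, odds ratio 0.179, exact adjusted p = 0.0159), Drsl6 (106) and PGRP-LD (79.3), both nearer to starts of other genes (kst and Myt1). The immune list did not pass above the median signal (exact adjusted p = 0.113). None of 111 replication-dependent histone genes had a summit (exact adjusted p = 1.42e-10). Only 4 of the 111 had any ranked region within 1 kb, against 89.7% of all protein-coding genes, and with such genes as the background the histone list did not pass (exact adjusted p = 0.813). That background was chosen after seeing the data.

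The other lists did not pass in the main list, though some did in alternatives. Of 13 ecdysone response genes found, 6 had a summit (46.2%, exact adjusted p = 0.0743), led by ftz-f1 (218), EcR (157) and Eip75B (144). They passed in the pooled list, in replicate 2 alone and by nearest start (odds ratios 4.28, 4.27 and 7.95; Fisher's exact test, adjusted p = 0.0243, 0.0443 and 0.00122). Of 28 cell cycle genes 11 had one (39.3%, exact adjusted p = 0.0743), led by Cdk2 (275), CycB (217) and E2f2 (209). They passed in the pooled list, in replicate 1 alone, at 500 bp and by nearest start (exact adjusted p = 0.0118, 0.0282, 0.0238 and 0.0104). Of 48 proteasome genes 15 had one (31.2%, exact adjusted p = 0.142), with Prosalpha7 (507) and Rpn10 (338) after Rpn6. They passed in replicate 1 alone and at 500 bp (exact adjusted p = 0.0149 and 0.045). Among 20 Polycomb and Trithorax group genes 7 had one (exact adjusted p = 0.253), led by kis (315), Pc (239) and Su(z)2 (169). Germline genes had one in 4 of 12 cases (exact adjusted p = 0.425), with tud (263), stau (93.5) and bam (89.2).

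The lists of developmental regulators, each of 8 to 23 genes, did not pass in the main list. Of 23 segmentation genes found 6 had one (exact adjusted p = 0.639), led by bcd (124), cad (109) and odd (88.8). Of 22 neurogenesis genes 5 had one (exact adjusted p = 0.954), led by N (129), pros (127) and brat (122). Of 18 dorsoventral genes 3 had one (exact adjusted p = 1), namely pnr (112), rho (100.4) and Dr (62.0). Of 17 muscle genes 2 had one (exact adjusted p = 0.744), Mef2 (143) and sns (114.6). Of 8 Hox genes lab (94.7) had one and of 11 genes of the Enhancer of split complex E(spl)mbeta-HLH (87.4) and E(spl)m2-BFM (74.6) did, both lists with adjusted p = 1 in Fisher's exact test. By nearest start, with no limit on distance, the Hox list passed as more often (odds ratio 14.9, Fisher's exact test, adjusted p = 0.00137). Of 10 clock genes dco (111) had one (exact test, adjusted p = 0.898). Heat shock genes had one in 4 of 21 cases (exact adjusted p = 1), with Hsp68 (476), Hsc70-5 (189) and Hsc70-4 (109). The Hsp68 summit lay 935 bp from its start and nearer to SMC1. Of 27 Jonah and trypsin protease genes Jon65Ai (120) and Jon25Biii (100.99) had one (exact adjusted p = 0.178), both nearer to other genes (tant and jet). By nearest start and at 500 bp the protease list passed as less often, with 0 genes (exact adjusted p = 0.0366 and 0.0237). Of 12 chorion and vitelline genes 0 had one (exact adjusted p = 0.242).

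**Figure D3:**
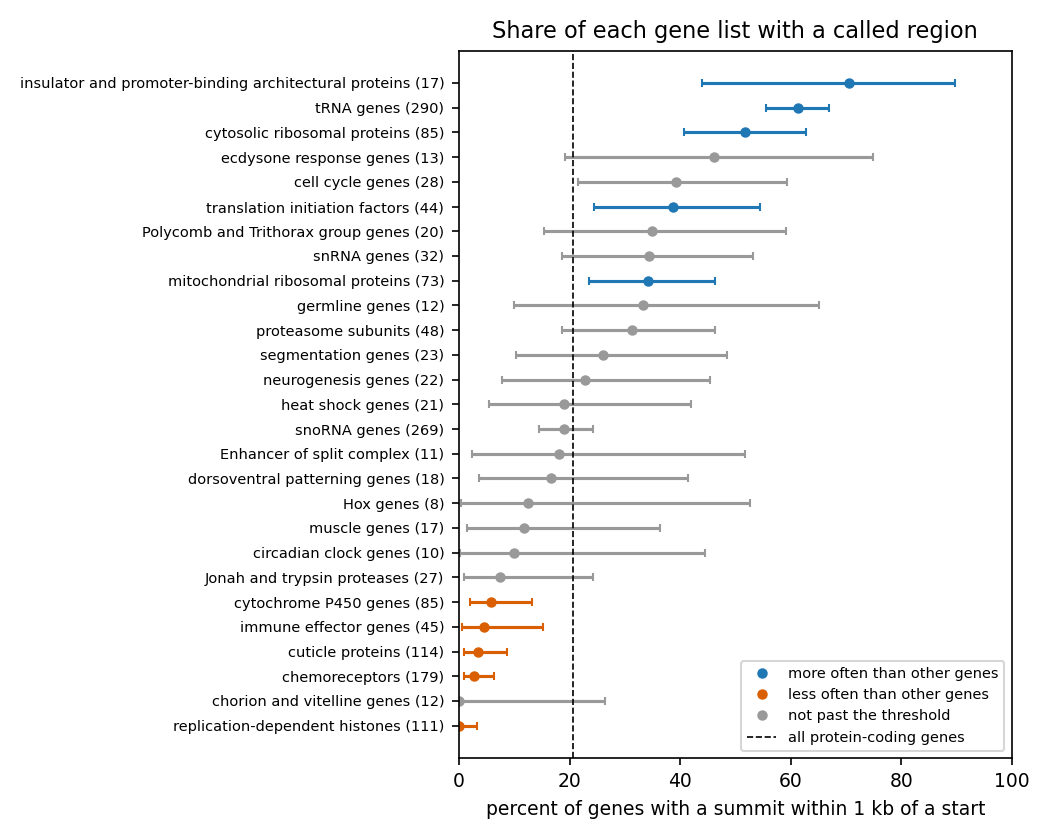
Percent of the genes of each list with a summit within 1 kb of a start (points, with exact binomial 95% intervals; number of genes in parentheses), with blue for lists above other genes, orange for lists below them and grey for lists that did not pass. The dashed line marks all protein-coding genes, 20.6%, and the insulator list stands highest at 70.6%.

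DRE, the BEAF-32 core and Motif 1 were the centred sequences with the lowest p. The DNA replication-related element TATCGATA (DRE), bound by DREF and by BEAF-32, lay within 50 bp of the summit in 363 of 2747 regions (13.2%, 95% interval 11.97 to 14.5) and in flanks of the same length in 36 (1.31%). This was a ratio of 10.1 (two-sided exact McNemar test, adjusted p = 9.07e-72 over 18 sequences). The shorter BEAF-32 core CGATA lay at 1186 centres and 414 flanks (ratio 2.86, exact adjusted p = 1.32e-123). Motif 1, GGTCACACT, bound by M1BP, lay at 102 centres and 9 flanks (ratio 11.3, exact adjusted p = 1.92e-20). Ohler motif 7, CATCGCTA, lay at 36 and 8 (ratio 4.5, exact adjusted p = 4.58e-05). The core GCCAT of Pho sites lay at 608 and 417 (ratio 1.46, exact adjusted p = 1.27e-10) and the E-box CAGCTG at 204 and 120 (ratio 1.70, adjusted p = 3.62e-06). GCCAT also lies in the reverse complement of AGATGGCG, described below at summits away from starts, so those matches count as Pho cores too. The AP-1 site TGACTCA lay at 32 centres and 13 flanks (exact adjusted p = 0.0081) and CACCTG at 147 and 112 (adjusted p = 0.0331). Neither of these passed in either replicate alone.

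The TATA box, TAATTA, AGATAA and 4 other sequences lay in the flanks more than in the centres. The TATA box TATAAA was found at 215 centres and 467 flanks (ratio 0.46, exact adjusted p = 5.24e-25), the homeodomain site TAATTA at 74 and 185 (ratio 0.4, adjusted p = 5.98e-12) and the GATA site AGATAA at 92 and 187 (ratio 0.492, adjusted p = 7.87e-09). The Zelda site CAGGTAG was found at 7 and 19 (exact adjusted p = 0.0348) and the Hox/TALE site TGATTGAT at 5 and 17 (adjusted p = 0.0234). Neither of those passed in either replicate alone. Runs of 8 adenines (86 and 185, exact adjusted p = 1.82e-09) and CA repeats (64 and 109, adjusted p = 0.000936) were also flank-rich. The GAGA sequence GAGAGAG (53 and 63, exact adjusted p = 0.382), the E-box CACGTG (58 and 43, adjusted p = 0.184) and the Su(H) site GTGGGAA (36 and 27, adjusted p = 0.324) did not pass. CACGTG passed as centred in the pooled list and at summits away from starts, and GTGGGAA against its reversal (exact adjusted p = 0.0109, 0.013 and 0.0409). Against its own reversal CACGTG passed as less frequent (ratio 0.674, exact adjusted p = 0.0318). When each sequence was compared with its own reversal in the centres, TAATTA, AGATAA, TGATTGAT and TGACTCA no longer passed (exact adjusted p = 0.0944, 0.222, 0.225 and 0.899).

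**Figure D4:**
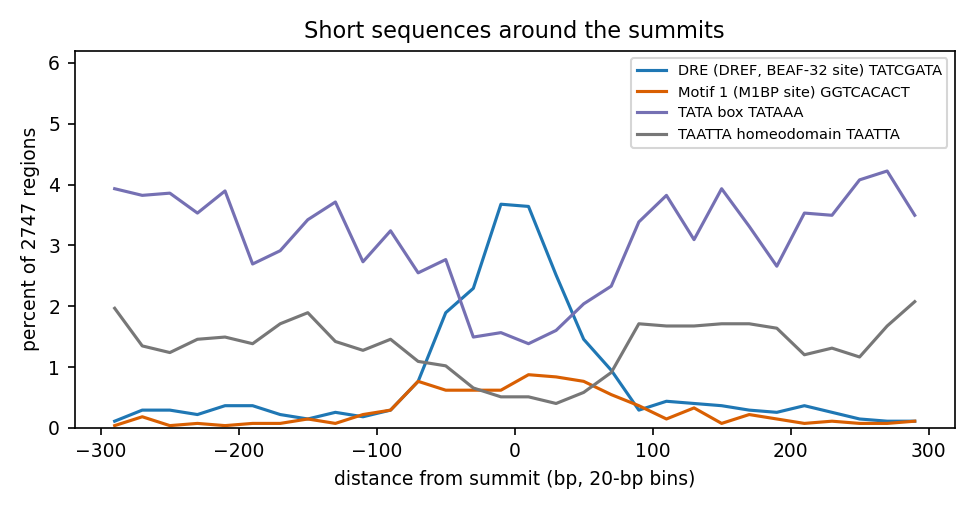
Percent of the 2747 regions of the main list with each sequence, on either strand, in 20-bp bins by distance from the summit in bp. TATCGATA and GGTCACACT peak at the summit, while TATAAA and TAATTA dip there.

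A search over all 8-mers, without a sequence given in advance, returned the same elements. The 20 8-mers with the lowest p on 2L and 2R (1180 regions) were tested again on the 1567 regions of the other chromosomes, and all 20 passed (one-sided exact McNemar test, Benjamini-Hochberg over the 20). Of the 20, 19 held the bases CGAT or ATCG of the DRE core. The strongest, ATCGATAG, lay at 233 centres and 19 flanks on the other chromosomes (exact adjusted p = 9.92e-49), and TATCGATA lay at 223 and 24 (adjusted p = 2.14e-44). The other was GGTCACAC, part of Motif 1, at 73 centres and 11 flanks (exact adjusted p = 1.41e-12).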

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

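The tests of extra copies, of the shared sequence, of transfer RNA genes and of the chromosome-wide ratio were chosen only after the results were seen. The tests of repeated sequence, GC content, DRE at promoters that were not called and windows of chromosome 4 were written down before their values, the last of these after the chromosome totals were known. The explanation by GC content was narrowed in its wording to GC-rich promoters after its result was seen, with the prediction unchanged. With 1 group in the design, no biological explanation was tested for any of these patterns.

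The 3 regions at Kr-h1 are 13437.1, 5917 and 2843 in signal, against 1426 for the next region. Extra copies of the whole stretch, enough to give these signals, are argued against. The 83 other ranked regions within 20 kb had a median signal only 1.14 times that of the genome (bootstrap 95% interval 0.977 to 1.43). A small gain in copies is not excluded, as the interval reaches 1.43. Other regions within 20 kb of Kr-h1 were also called, the strongest with a signal of 416. Repeated sequence is argued against too, as 0 of the 1119 36-mers in the 3 regions (0%) occurred more than once on the main chromosomes. The short pattern tried, shared by the 3 regions, is not enough by itself for a called region. Other shared sequences were not tested. The pattern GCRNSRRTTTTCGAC (R is A or G, S is C or G, N any base) has 4 matches in the 3 regions and 21 elsewhere, of which 0 lay in called regions (upper 95% bound 16.1%) and 8 in ranked regions. Recognition by the antibody of something other than the tagged protein was not tested and stays open.

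Cytosolic ribosomal protein genes and DRE stood out in the list. Recovery of highly transcribed starts of any kind stays open. The odds ratio of transfer RNA genes, 7.37, was known before the test was written and so lends it no support. Those of snoRNA and heat shock genes were 1.04 and 0.909, but transcription was not measured here, so neither decides the question. The snoRNA ratio was also 0.427 at 500 bp and 2.14 at 2 kb. DRE lay within 50 bp of the summit at 16.1% of 2188 called and 1.41% of 11061 uncalled promoter regions. The odds ratio was 13.4 (Fisher's exact p = 1.93e-163). The uncalled regions were ranked ones that missed the IDR limit, over 1 kb from any called summit and thinned to the strongest per 1 kb. Their summits could lie anywhere within 500 bp of a start and were not matched to called summits in distance. Recovery of promoters whatever their sequence is therefore not decided by this test. The median GC content of called regions was lower than that of the same uncalled regions (41.9% against 47.8%, difference -5.98 points, bootstrap 95% interval -6.31 to -5.65). This gives no sign of a preference for GC-rich promoters, with the same limit on where the uncalled summits lie. A preference for AT-rich fragments, and proteins that bind DRE bringing the tagged protein along, were not tested and stay open.

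Chromosome 4 had 784 ranked regions in replicate 1 and 87 in replicate 2, which came up because the ranked lists of single replicates enter no location comparison. A shorter ranked list in replicate 2 is argued against, since off chromosome 4 it held 1.09 times as many regions as replicate 1. The deficit ran over the whole chromosome, with fewer regions in replicate 2 in 7 of 7 windows of up to 200 kb (100%). It was smallest in the last, shorter window (23 regions in replicate 1 and 13 in replicate 2). A difference in copies of chromosome 4, or in the control library's coverage of it, may give such a pattern, and the lists hold no coverage to decide between them.

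The ranked list between replicates holds 142 regions that met the IDR limit and are not in the thresholded list, 69 of them on 3R. The strongest lay on an unplaced sequence (signal 939), and those next in signal lay by the starts of Bicra (524), Ubc6 (510), osa (490.3) and kibra (425).

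The window on X was chosen after its regions had been seen, and was widened once from a shorter stretch. In the last 300 kb of X, next to the centromere, replicate 2 had 190 ranked regions and replicate 1 had 14, with median signals of 1.51 and 0.744 times each list's median. Of those in replicate 2, 50 met the IDR limit and 0 are in its thresholded list.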

How the results depend on the processing

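Alternatives with ranked regions as the expectation or background, without repeat-masked sequence, with promoter or other summits alone, and with tagged-gene regions counted by summit were chosen after seeing the data. The promoter share kept its direction and call in all 8 alternatives run (74.1% to 87.0%), as did the replicate overlap in all 4 (67.7% to 76.4%). All 20 sequences chosen also passed with 6-mers in place of 8-mers and with the discovery and test chromosomes swapped. Without one replicate, the promoter signal difference was 2.22 to 14.6, and the call was lost without replicate 1. The list above the median signal holds 1376 regions by construction. There, 3 chromosomes passed in place of 5 and 3 gene lists stood higher in place of 5, with fewer regions tested. Against starts 2 chromosomes passed, and without repeat-masked sequence 3. The share of regions above the tagged gene's strongest was 44.0% in the pooled list, 55.5% without replicate 2, 1.31% and 1.24% in the ranked lists between replicates and of pooled reads, 1.39% and 2.80% in those of replicates 1 and 2, and 89.0% by summit. Counting by summit was the first version computed, and was corrected to the definition fixed at the start. Without replicate 1 it has no value, as no region was near. The signal rho was 0.473 in the pooled list and 0.304 over all ranked regions. Fixed sequences called in flanks fell from 7 to 3 against reversals. Only TATA and Zelda of the 7 held, 3 were lost, 2 had no usable reversal, and CACGTG was new. At summits away from starts 2 were centred and 4 in flanks, in place of 8 and 7. The direction turned for snoRNA genes at 500 bp (odds ratio 0.427) and by nearest start (0.271), both past the threshold. By nearest start it also turned for Hox genes (14.9, past it) and mitochondrial ribosomal proteins (0.786). For CACCTG it turned without replicate 2 (0.952) but not without replicate 1 (1.44). Against its reversal CACGTG turned as well (0.674, past it). Away from starts the direction turned for Ohler motif 7 (0), the Hox/TALE site (1.5) and CA repeats (1.62). The cause of these turns was not tested. Only members that passed in the main list or in the alternative were counted next, not all those run. Of the odds ratios of single lists 69 of 95 kept their call and direction, of single sequences 86 of 122, and of single chromosomes 21 of 31. No depth limit can be given without counts. No paired analysis was possible because the series has 1 group.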

Other observations

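The test of 8-mers away from starts was chosen only after the result was seen, and that of signal with DRE was written down first.

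Regions away from starts carried another sequence. Among the 559 summits over 500 bp from any start, AGATGGCG lay at 45 centres and 1 flank, and the overlapping GATGGCGC, ATGGCGCC and TGGCGCCA at 42 and 3, 30 and 0, and 29 and 0. Together they read AGATGGCGCCA, which resembles the core of the sequence bound by the insulator protein CTCF in Drosophila. Chosen on 233 regions of 2L and 2R, AGATGGCG lay at 30 centres and 1 flank among 326 regions elsewhere (one-sided exact McNemar test, adjusted p = 3.73e-08), and 16 of the 20 8-mers chosen passed there. This is consistent with a CTCF-type sequence at part of the distal regions, a hypothesis found on these data. Regions with AGATGGCG had a median signal of 109, against 79.7 for the other 514. The strongest lay between genes on 2R, 3401 bp from slbo (24337560 to 24337855, signal 212), and in an antisense RNA exon at CG9171 on 2L (198). Another with the sequence lay in a coding exon of otp on 2R (signal 190). Also centred were ACTGCTTG (34 and 3) and ATGTAGAA (25 and 1), for which no binding protein is named here. The fixed DRE sequence did not pass at these summits (ratio 5, exact adjusted p = 0.0552).

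At promoters, regions with DRE had higher signals. The median was 143 in the 353 promoter regions with TATCGATA within 50 bp of the summit and 103 in the 1835 without. The difference was 40.0 (permutation p = 1e-05, the smallest it can give). The prediction, a higher median with DRE, was met, but it named no cause. Beside DRE, Motif 1 (4.57% against 0.868%, odds ratio 5.47, exact adjusted p = 2.08e-28) and Ohler motif 7 (1.65% against 0.28%, odds ratio 5.95, adjusted p = 1.41e-11) were more frequent at called than at uncalled promoter regions. Uncalled summits were not matched to called ones in distance to a start, in this and the comparisons that follow. Less frequent were the Zelda site (0.183% against 0.796%, exact adjusted p = 0.00213), the Hox/TALE site (odds ratio 0.174, adjusted p = 0.008) and CACCTG (0.768, adjusted p = 0.0341). CACCTG was centred over all summits but did not pass at promoter summits alone (ratio 1.25, exact McNemar test, adjusted p = 0.144). The Pho core and CAGCTG, also centred, did not pass between called and uncalled promoter regions (odds ratios 0.894 and 1.09, exact adjusted p = 0.098 and 0.415). The TATA box, low at summits, did not pass between them either (7.54% against 7.15%, exact adjusted p = 0.593).

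The 20-kb window around CG42726 had a median ranked signal 1.62 times that of the genome in the list between replicates, and 31 of 5367 windows were higher. Of the 475 windows with at least as many annotated starts, 10 were higher. The ratio was 1.53 in replicate 1, where 80 of 5184 windows were higher, and 1.46 in replicate 2, where 59 of 5698 were. Among windows with at least as many starts, 28 of 478 were higher in replicate 1 and 13 of 471 in replicate 2.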
